A study of Mus musculus with 2 samples.

How the data were processed

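Messenger RNA of testes from 17 day old mice of mixed 129SV and C57BL background was measured on Affymetrix mouse genome 430A 2.0 arrays, per the labels, with 1 array for wild type and 1 for UBR2-/- and 2 testes named for each genotype. On such an array biotin-labelled RNA binds short probes, and a set of probes gives a signal for a transcript. The deposited values are linear probe set intensities (signals) on the authors' scale, and MAS5, a method that turns probe brightness into 1 signal per probe set, is named in the submitters' processing notes; its version, settings and detection calls are not given in the sources used here. Each deposited array had a 2% trimmed mean of 150.04, which shows a scaling of both arrays to a common level before deposit, and this scaling was kept. No genome build is named in the sources used here.

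The arrays held 22690 probe sets, of which 64 were controls. Of the other 22626, 20380 had 1 gene symbol in the platform annotation, which can be old, 691 had several and 1555 had none; only those with 1 symbol were used. Through the Entrez identifier 20351 of them matched the GRCm38.p6 gene table, which served only for names and chromosomes, and 29 did not. Some members of the fixed lists were found through older names, among them Tex13b, which the table lists under the name Tex13. The floor was the 40th percentile of each array, 24.4 for wild type and 24.7 for UBR2-/-. Lower signals were raised to it before the log2 ratio was taken, and a gene at the floor on 1 array is given as at least N-fold, the bright signal over the floor of the other array. Each gene was represented by its brightest probe set, and 8091 of 12393 genes with a mean signal at or above the mean floor were compared; 3040 of them had several probe sets. For 124 genes the wild type array and for 172 the UBR2-/- array was at the floor. Probe set disagreement was measured over 2893 genes, as the SD of 1 probe set's log2 ratio, scaled down from the difference between pairs of probe sets of the same gene.

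With 1 array per genotype no test across samples exists, and no p-value or standard error is given. Counts use a threshold of 2-fold. A gene list or chromosome is described by its median log2 ratio and by the percentile of this median among 10000 random lists of the same size, matched on mean signal in 10 bins; random lists for chromosomes were drawn from autosomal genes. Before the data were examined, 24 gene lists were fixed, for germ cell stages, somatic cell types, ubiquitin and DNA damage pathways, stress responses, control genes and sex-linked groups; 2 of them had fewer than 4 compared members and got no median. Named genes were also chosen by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest log2 ratios among genes above the floor on both arrays, with the brighter signal at or above the 60th percentile of its array and all probe sets on the same side of 0. It adds the 5 brightest genes in each direction that were at the floor on the other array with a bound of at least 2-fold, Ubr2 with the N-end rule list, and from each list the first 2 compared members and the 3 farthest from 0. Genes outside the rule are named as such where they appear, except list members given to complete a small group or to show members on the other side of 0.

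The precision is limited by the number of arrays. As a check of RNA quality, the 3' to 5' ratio of Actb was 1.75 on the wild type and 1.64 on the UBR2-/- array, and that of Gapdh was 0.796 and 0.822. The procedure was tested on simulated data for the UBR2-/- over wild type comparison, with the wild type signals, noise and 200 lowered genes. The noise was independent for each probe set and held no difference between arrays or animals. Lowered and raised genes were drawn from those with a wild type signal over 100. At a log2 change of -1.5, 99% of 100 genes were found at least 2-fold lower, and at a change of -3, 100%. With this noise 0% of 7845 unchanged genes were 2-fold off, over 8085 genes in this step. These shares check the calculation and are no error rates for the real arrays. A list of 40 genes raised by 0.3 had a median of 0.30 at percentile 100, and 5% of 300 unchanged lists fell outside the central 95%. The unchanged lists were random genes with independent noise, so their share was set by the design. It does not cover lists of genes that vary together.

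Alternatives fixed before the data were examined were scaling to the array median, quantile normalization, loess of the ratio on signal (span 0.3), floors at the 25th and 60th percentiles, no floor with a pseudocount of 10, the mean over probe sets, leaving out probe sets that can bind several transcripts (those whose names end in _s_at, _x_at or _a_at), thresholds of 1.5-fold and 3-fold, unmatched random lists, and 2 narrower sets of X-linked genes. Scaling to the spike-in controls, and the retrogene list without members of the pachytene list, were added after seeing the data. Bootstrap intervals of differences between medians used 10000 draws of genes; they describe the spread between genes, not between animals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.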

Results

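Messenger RNA was measured in testes of 17 day old mice, an age at which the first wave of spermatogenesis has brought many germ cells into the pachytene stage of meiosis and hardly any beyond it. Wild type testes were compared with UBR2-/- testes, which lack UBR2, a ubiquitin ligase of the N-end rule pathway that has been studied for its part in male meiosis and in histone ubiquitination. Each genotype was represented by 1 oligonucleotide array (n = 1), for which the labels name 2 testes from different littermates. Whether their RNA was pooled is not given in the sources used here. The median signal over 22626 probe sets was 48.7 on the wild type array and 48.75 on the UBR2-/- array, and 8091 genes were bright enough to be compared. With 1 array per genotype there was no replicate check, no test was possible, and each difference below describes these 2 arrays and not the genotypes in general. The SD of 1 probe set's log2 ratio, derived from pairs of probe sets of the same gene, was 0.26 for dim, 0.18 for intermediate and 0.14 for bright probe sets. Both probe sets of a pair read the same 2 arrays, so this SD leaves out error between arrays or animals. Ratios are UBR2-/- over wild type.

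The targeted gene was examined first. Ubr2 had a signal of 57.2 on the wild type array and 14.3 on the UBR2-/- array, below that array's floor of 24.7, which makes it at least 2.32-fold lower. It was read by 1 probe set, and its position relative to the deleted part of the gene is not given in the sources used here, so this is a limited check of the labels. Ubr1, the closest relative of UBR2, had a log2 ratio of 0.07, the ubiquitin ligases Ubr3 and Ubr4 had 0.04 and 0.22, the related Ubr7 had 0.15, and Ate1, which attaches arginine to protein ends, had -0.12. The ubiquitin-conjugating enzymes that work with UBR2 lay apart, with 0.80 for the X-linked Ube2a and -0.24 for its autosomal relative Ube2b. Tex19.1, whose protein binds UBR2 in germ cells, had 0.33, the amidase gene Ntan1 had 0.27 and Rgs5, a substrate of the pathway, had -0.57. Of the 11 compared members, 0 were at least 2-fold higher, 1 (Ubr2) was at least 2-fold lower and 10 lay between. The median of the list was 0.07, at percentile 51.3 of 10000 random lists of the same size matched on signal.

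Across the genome the differences were lopsided: 285 genes were at least 2-fold lower on the UBR2-/- array and 28 were at least 2-fold higher. Several of the genes farthest below 0 are known from sperm. Adam5, a sperm surface protein of the ADAM family, was 23.7-fold lower, with signals of 681.8 and 28.8 (log2 ratio -4.57). Fbp1, an enzyme of gluconeogenesis, was 18.1-fold lower, Crisp2, a protein of the acrosome and sperm tail, was 14.9-fold lower, and Pgam2, an isoform of a glycolytic enzyme, was 12.7-fold lower. Spata4 was 12.3-fold lower, Lrrc23, a radial spoke protein of the sperm tail, 11.4-fold, Cetn1, a centrin of the centriole, 11.4-fold by its brightest probe set (log2 ratios of -3.51 and -2.21 in its 2 probe sets), and Cct6b, a testis subunit of the CCT chaperonin, 11.2-fold. Clec2m, the glycerol kinase gene Gk2, Fhl4 and the poly(A)-binding protein gene Pabpc2 completed the 12 lowest, with log2 ratios of -3.42, -3.38, -3.18 and -3.12. Some of the UBR2-/- signals lay just above the floor of 24.7, with 24.9 for Cct6b, 25.2 for Pabpc2 and 26 for Lrrc23, so these folds are little more than bounds. Among genes below the floor on the UBR2-/- array, Adam3, a sperm protein needed for binding the egg coat, was at least 10.8-fold lower, Catsperz, a part of the sperm calcium channel, at least 10.4-fold lower and Cmtm2a at least 9.54-fold lower. The clone-named genes 1700074P13Rik and 4930544G11Rik were at least 16.9-fold and at least 11.3-fold lower.

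The genes farthest above 0 were fewer and closer to 0, and 6 of the 12 highest lay on the X or Y chromosome. Ccnb3, an X-linked cyclin of early meiosis, had signals of 116.3 and 424.7 and was 3.65-fold higher on the UBR2-/- array. The X-linked transketolase-like gene Tktl1 was 2.71-fold higher, and Magea5 and Piga, also X-linked, were 2.07-fold and 2.06-fold higher. The other probe set of Piga had a log2 ratio of 0.66. The Y-linked genes Zfy2, a zinc finger transcription factor, and Usp9y, a deubiquitinase, were 2.62-fold and 2.18-fold higher. The 6 autosomal genes were Ece1 (3.10-fold), the protamine gene Prm1 (2.66-fold), Tnfrsf12a (2.61-fold), Ifitm1 (2.46-fold), Dnajc12 (2.26-fold) and Cyp2s1 (2.07-fold). Prm1 was dim at 35.3 and 94, and its 3 probe sets ranged from 0.35 to 1.55. Among genes below the floor on the wild type array, the defensin gene Defb15 was at least 4.98-fold higher, the X-linked Ribc1 at least 2.43-fold and Cysrt1 at least 2.22-fold, while Ly96 and the X-linked Enox2 were at their bound of about 2-fold.

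Over all 8091 compared genes the median log2 ratio was 0.07, with quartiles of -0.17 and 0.28, and Pearson's r of the log2 signals of both arrays across the 7795 genes above the floor on both was 0.957. At a threshold of 3-fold, 121 genes were lower and 3 higher, and 70 genes were at least 4-fold lower against 1 at least 4-fold higher. The bacterial and phage control transcripts read by 42 probe sets had a median log2 ratio of 0.35, so scaling on them instead of the deposited scaling moves the median of all genes by -0.35 and gives 7 genes at least 2-fold higher and 528 lower. Percentiles of gene groups, and counts said to be above or below the median of all genes, are relative to all compared genes. Log2 ratios of single genes are on the deposited scale, and small values above 0 turn with spike-in scaling.

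**Figure D1:**
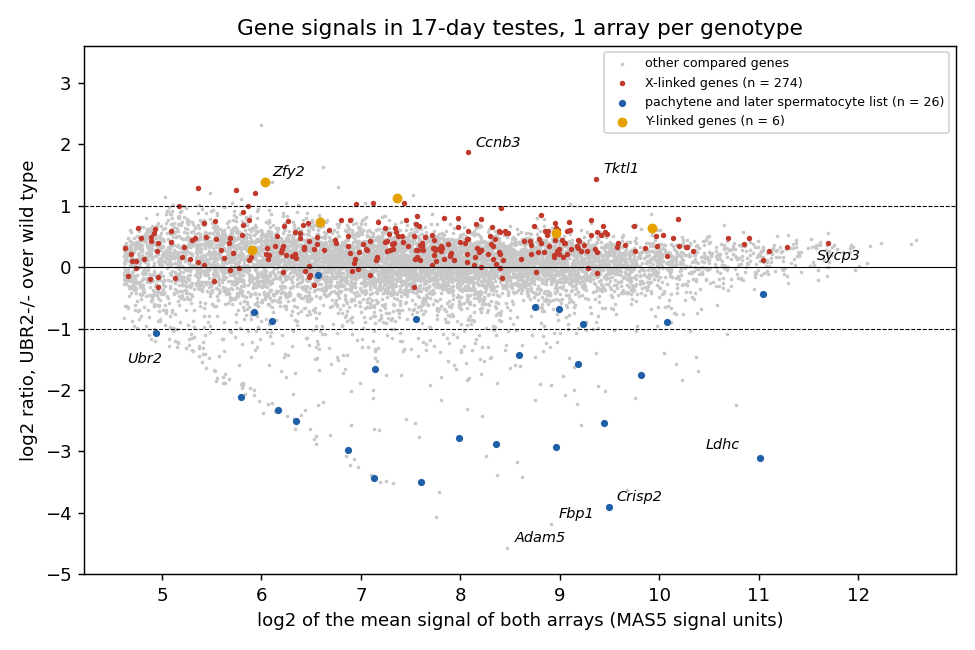
Each point is 1 of the 8091 compared genes; the x axis is the log2 of the mean signal of both arrays in MAS5 signal units and the y axis is the log2 ratio of UBR2-/- over wild type, with dashed lines at 2-fold. All 26 genes of the pachytene and later spermatocyte list (blue) lie below 0, while 251 of 274 X-linked genes (red) and 6 of 6 Y-linked genes (orange) lie above 0; with spike-in scaling every point would lie about 0.35 lower, and 135 of 273 X-linked and 5 of 6 Y-linked genes would lie above 0.

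Genes used in late spermatocytes were far lower on the UBR2-/- array, while most genes that start earlier in meiosis lay within 2-fold and somewhat below all genes. In the list of pachytene and later spermatocyte genes, 17 of 26 compared members were at least 2-fold lower, 0 were at least 2-fold higher and 9 lay between. Ldhc, the lactate dehydrogenase of germ cells, had signals of 3709.3 and 430.5 and was 8.62-fold lower, and Hspa2, a chaperone that late spermatocytes need, was 1.87-fold lower. The list's median was -1.71, at percentile 0 of the matched random lists. Of the 21 compared genes of early meiotic prophase, 1 was at least 2-fold lower and 20 lay between, with 16 below and 5 above the median of all genes and a median of -0.06 at percentile 3.80. Loess took it outside the central 95% of random lists, to percentile 2.01. Sycp3 and Sycp1, which build the axes and the central part of the synaptonemal complex, had log2 ratios of 0.02 and -0.11, with signals of 2954.7 and 2342.1 on the UBR2-/- array. Quantile normalization turned that of Sycp3 to -0.18. The member that was 2-fold lower was Spo11, the enzyme that makes meiotic DNA breaks, at -1.27, followed by Psmc3ip at -0.82 and the mismatch repair gene Mlh3 at -0.61, both with parts in meiotic recombination. Spermatid genes were mostly too dim at this age, with 16 members below the floor rule and 7 compared. Of these, 3 were at least 2-fold lower, including Tekt1 of the sperm tail at -2.57 and the sperm ion channel gene Catsper2 at -1.22, 1 was higher (Prm1) and 3 lay between, and the median was -0.12 at percentile 9.50. This list fell below the central 95% of random lists under 5 of 10 alternatives, and the mean over probe sets moved its excess over random lists from -0.21 to -0.86. The median of this list was the value of Odf2 by its brightest probe set. The 3 probe sets of Odf2 disagreed, ranging from -2.25 to -0.12.

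Sertoli cell and peritubular myoid genes lay above all genes, while spermatogonia, Leydig and endothelial genes had medians above that of all genes and within the central 95% of random lists. The spermatogonia list lay outside it under 3 of 10 alternatives. Of 17 compared spermatogonia genes, 1 was at least 2-fold lower, Id4, a transcriptional regulator of stem spermatogonia, at -1.07 in the brightest of 3 probe sets that ranged up to -0.65, 0 were 2-fold higher and 16 lay between, and the median was 0.22 at percentile 91.8. Within this list Dmrtb1 had -0.82, Cdh1 had 0.53 and Zbtb16, a stem cell transcription factor, had 0.02. The probe sets of the receptor gene Kit disagreed, ranging from -0.07 to 0.97. The Sertoli cell list had a median of 0.29 at percentile 99.9 over 24 genes, with Sox9, which drives Sertoli cell fate, at 0.29 and the receptor gene Fshr at 0.58. Its 1 member at least 2-fold lower was Amh, the hormone of immature Sertoli cells, at -1.23, and the other 23 lay between. Amh was read by 1 dim probe set, with signals of 59.7 on the wild type and 25.5 on the UBR2-/- array, just above that array's floor of 24.7. A second list of Sertoli genes that respond to germ cell loss had a median of 0.40 at percentile 99.98 over 14 genes, 7 of them also in the first Sertoli list and 0 beyond 2-fold. Its tight junction genes Cldn5 and Cldn11 had 0.94 and 0.41, and Gdnf, a growth factor for spermatogonial stem cells, was at least 1.59-fold higher. All 10 compared peritubular myoid genes lay above the median of all genes, with a median of 0.50 at percentile 100 and 0 beyond 2-fold. The contractile genes Acta2, Myh11, Tpm2 and Mylk had 0.49, 0.64, 0.59 and 0.57. Of 13 Leydig cell genes 0 were beyond 2-fold and the median was 0.23 at percentile 93.1, with the steroidogenic genes going both ways: Star had 0.80 with 3 probe sets from 0.11 to 0.84, Cyp17a1 0.12, Akr1c14 -0.51 and Cyp11a1, which starts steroid synthesis, -0.59. The 8 endothelial genes had a median of 0.31 at percentile 89.6 and 0 beyond 2-fold. Of these, 5 lay above the median of all genes, among them Cldn5, shared with the Sertoli response list, at 0.94, Cdh5 at 0.41 and Kdr at least 1.51-fold higher, and 3 lay below it, with Esam at -0.30, Tek at -0.12 and Pecam1 at the floor on the UBR2-/- array. Macrophage and leukocyte genes were not above all genes: 13 of 16 lay below the median of all genes, 0 were beyond 2-fold and the median was -0.08 at percentile 7.54, with Csf1r, a receptor of macrophages, at -0.02, Adgre1 at -0.24, Fcer1g at -0.43 and Laptm5 at -0.39 in its brightest and 0.10 in its other probe set. The member farthest from 0 went the other way, Ptprc, a leukocyte surface phosphatase, which was at least 1.54-fold higher. Of the erythrocyte list 0 members were bright enough to be compared.

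In the list for the piRNA pathway and retrotransposon control, 2 of 9 compared members were at least 2-fold lower, 0 were higher and 7 lay between, and the median was -0.62 at percentile 0. Ddx25, a germ cell RNA helicase, was 3.14-fold lower and Tdrd1, a scaffold of the piRNA pathway, was 2.30-fold lower, while Ddx4 and Piwil2 had -0.77 and -0.55, Mov10l1 had -0.13 and Tex19.1, also in the N-end rule list, was the 1 member above 0. In the chromatin ubiquitination and meiotic DNA damage list 0 of 23 members were beyond 2-fold and the median was -0.04 at percentile 6.14. Its members went both ways, with 10 above the median of all genes and 13 below it. H2ax, the histone that marks DNA damage, and the ubiquitin ligases Rnf8 and Rad18 had -0.11, -0.21 and -0.59, the autosomal Cbx2, Chek2 and Brca1 had 0.30, 0.28 and 0.23, and the X-linked Scml2 and Huwe1 had 0.57 and 0.44. Of 8 histone and histone reader genes 1 was at least 2-fold lower, Brdt, a bromodomain protein of spermatocytes, at -1.09 in the brightest and -0.32 in the other probe set, and the median was -0.10 at percentile 10.3. H2az1 had -0.17, H2az2 0.22 and Cdyl 0.35. Of 34 proteasome genes 33 lay within 2-fold and the median was 0.03 at percentile 23.8. The remaining member, the germ cell subunit Psma8, was 2.64-fold lower, while Psma1, Psma2, Psma5 and Psmc3 had -0.03, 0.26, 0.40 and -0.40.

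Of 16 genes of the p53 response and apoptosis 0 were beyond 2-fold, 9 lay above and 7 below the median of all genes, and the median was 0.22 at percentile 90.5, with the cell death genes Pmaip1 and Bcl2l11 at 0.79 and 0.55, Gadd45a at 0.69 and the cell cycle inhibitor Cdkn1a at 0.23, against Mdm2, which restrains p53, at -0.23 and Btg2 at -0.19. Its excess over random lists turned to -0.035 with a pseudocount and -0.019 with the mean over probe sets. The 8 interferon response genes, all within 2-fold, had a median of 0.37 at percentile 95.7, with Bst2 at 0.83, Ifih1 at 0.50, Irf7 at least 1.32-fold higher and Stat2 at -0.50. Its excess of 0.27 over random lists was 0.024 with the floor at the 25th percentile and turned to -0.11 with a pseudocount. The 14 ordinary control genes, 0 of them beyond 2-fold, had a median of 0.24 at percentile 97.8, just outside the central 95% of random lists, with Actb at 0.18, Tubb5 at 0.41, Eef1a1 at 0.38 and Tbp at -0.47. The other probe set of Tubb5 had -0.24, and quantile normalization took Eef1a1 to 0. The place of the list outside that range was lost under 7 of 10 alternatives. Of 22 lists with at least 4 compared members, 7 lay above and 3 below the central 95% of their random lists. If genes varied independently, 1.1 would be expected. Genes of a real list can vary together, which random lists do not keep, so that number can be too low. Of 19 autosomes, 4 also lay outside their random ranges. Lists share genes, and these percentiles describe these arrays only.

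**Figure D2:**
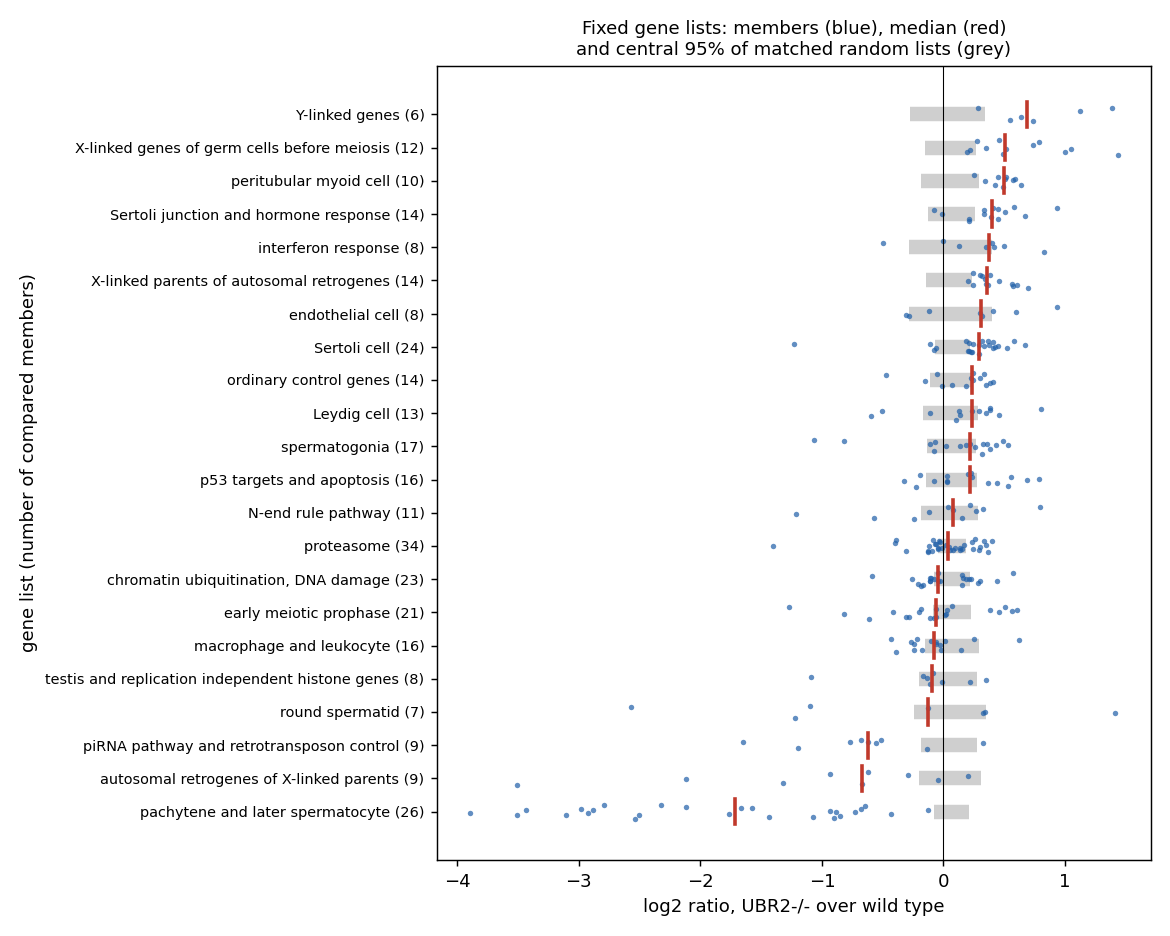
Each row is 1 fixed gene list with its number of compared members, each blue point is 1 gene, the red line is the list's median and the grey bar the central 95% of medians of 10000 random lists matched on signal; the x axis is the log2 ratio of UBR2-/- over wild type. The pachytene and later spermatocyte list has its median at -1.71 and the Y-linked list at 0.69; spike-in scaling would move every point and bar by about -0.35 and so turn many small values above 0 to values below 0.

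The sex chromosomes were then compared with the autosomes, since silencing of both in pachytene spermatocytes is a known feature of male meiosis. X-linked genes were higher than autosomal genes as a group. The median log2 ratio of 274 X-linked genes was 0.35, or 1.27-fold, against 0.06 for 7801 autosomal genes, and 245 of the 274 (89.4%) lay above the autosomal median. At least 2-fold higher were 9 X-linked genes against 0 lower, while of the autosomal genes 17 were higher and 285 lower. Random autosomal lists of the same size and signal had a central 95% range of 0.01 to 0.10, which places the X chromosome at percentile 100, with an excess of 0.29. The 6 compared Y-linked genes had a median of 0.69, or 1.61-fold, at percentile 100, with Zfy2 and Usp9y at least 2-fold higher and 4 between. These 4 were Uty at 0.73, Uba1y at 0.64, the translation factor gene Eif2s3y at 0.55 and the histone demethylase gene Kdm5d at 0.28. Autosome medians ran from 0.01 to 0.11, and 4 of 19 lay outside their random range, chromosome 11 by a narrow margin at percentile 2.35. With spike-in scaling the X median was -0.0027 and the autosomal median -0.29, so the raw direction of X-linked genes depends on scaling while their place above autosomal genes does not.

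**Figure D3:**
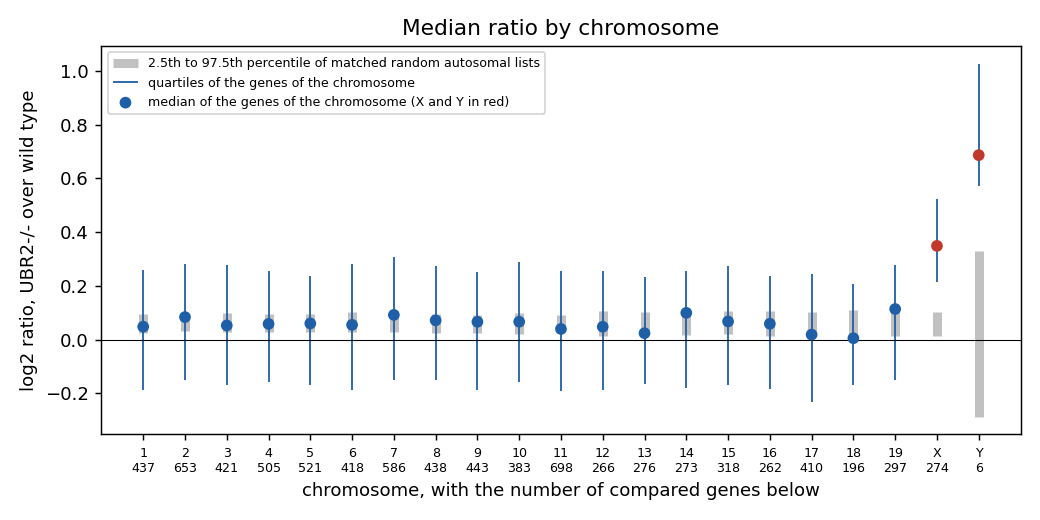
Points give the median log2 ratio of UBR2-/- over wild type of the compared genes on each chromosome (number of genes below each name), thin lines the quartiles of its genes, and grey bars the central 95% of medians of random autosomal lists matched on size and signal. The X (0.35) and Y (0.69) medians lie above their bars, while autosome medians lie between 0.01 and 0.11; spike-in scaling would lower all points and bars by about 0.35.

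X-linked genes used in germ cells before meiosis lay above the median of all genes in 12 of 12 cases, with 2 at least 2-fold higher (Tktl1 and Magea5) and 10 between. Usp26, a deubiquitinase of germ cells, was 1.99-fold higher and Tex11, a meiotic recombination factor, had a log2 ratio of 0.46, and the median of the list was 0.51 at percentile 100. Of the X-linked multicopy or spermatid list only Tsga8 was compared, at 1.25 from a signal of 31.7. X-linked genes with autosomal retrogenes, intronless copies that are used in spermatocytes, were all 14 above the median of all genes and within 2-fold, with a median of 0.36 at percentile 99.96. The random lists for these X-linked lists came from all compared genes, most of them autosomal. Their percentiles therefore carry the shift of the whole X chromosome (median 0.35), and neither list was set against other X-linked genes. Of the 9 autosomal retrogenes 3 were at least 2-fold lower and 6 lay between, with a median of -0.67 at percentile 0. Of the 9, 3 also belong to the pachytene and later spermatocyte list. In 7 of 7 pairs the X-linked parent had the higher log2 ratio, in the pairs of Pgk2 and Timm8a2 by a bound. These retrogenes were at the floor on the UBR2-/- array. The lowest of the 14 parents had 0.205 and the highest of the 9 retrogenes 0.203, so any pairing would give this outcome. The pairs thus add nothing to the difference between the 2 lists. Cetn2 had 0.70 and its retrogene Cetn1 -3.51 or -2.21 by probe set, the glycolytic gene Pgk1 had 0.24 while its retrogene Pgk2 was at least 4.35-fold lower, Pdha1 had 0.58 and Pdha2 -0.93, and Timm8a2 was at least 2.5-fold lower. Dynlt3, another parent, had 0.60. The 3 probe sets of Pgk1 ranged from -0.12 to 0.42, and spike-in scaling puts 7 of the 14 parents below 0.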

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

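No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out. Among main results under alternatives, 242 values stayed close to the main value and 27 moved. Close means a count within 1.5-fold, or a Ubr2 ratio within its probe set SD. For an excess it means within about 1 SD of the medians of random lists, so a close value can still cross the edge of the random range. The interferon and p53 lists, whose medians lay within the range of random lists, changed the sign of their excess in the settings given below. Lists and sex chromosomes are given here as the excess of the median over that of random lists. The X and Y chromosomes, the pachytene, Sertoli (both lists), myoid, piRNA, X-linked parent, premeiotic X-linked and retrogene lists lay outside the central 95% of random lists under each alternative run. The cause of the following shifts was not tested, except where the setting brings them by construction. That holds where fewer or other genes or probe sets enter and where the threshold changes. It also holds for spike-in scaling, which moves the median of all genes by -0.35. The count of genes at least 2-fold higher (28) was 17 with loess, 131 with the floor at the 25th percentile, 8 with the floor at the 60th, 56 with a pseudocount and 7 with spike-in scaling; the count of lower genes (285) was 152 with the 60th percentile floor and 528 with spike-in scaling. Of the genes beyond 2-fold, 8.95% were higher in the main setting and 24.6% with the 25th percentile floor. Thresholds of 1.5-fold and 3-fold gave 341 and 3 higher and 624 and 121 lower genes. Ubr2 had a log2 bound of -1.21 in the main setting and -1.56 with spike-in scaling, had a measured log2 ratio of -2 with the 25th percentile floor, which its UBR2-/- signal exceeds, and was not compared at the 60th. The pachytene excess was -1.57 with the 60th percentile floor, -1.62 with a pseudocount and -2.01 without probe sets that can bind several transcripts. The spermatid excess was -0.71 with the 60th percentile floor, -0.86 with the mean over probe sets and -0.47 without probe sets that can bind several transcripts. That list crossed the edge of the random range under 5 of 10 alternatives, and the spermatogonia, early meiotic, interferon and control lists crossed it in some settings. The X excess was 0.22 with a pseudocount. The control gene excess was 0.049 with quantile normalization and 0.066 without probe sets that can bind several transcripts. The interferon excess was 0.024 with the 25th percentile floor and -0.11 with a pseudocount, and the p53 excess was -0.035 with a pseudocount and -0.019 with the mean over probe sets. The retrogene excess was -0.52 without pachytene list members. Of 396 values for the 47 named genes beyond 2-fold, 0 reversed and 31 fell under 2-fold, in 15 genes. Dim signals limit the rest: 37 of 125 named genes were not compared at the 60th percentile floor.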

Other observations

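The gene groups in this paragraph and the next were chosen after the values were seen, and so were the genes named from them. They hold genes already seen to lie far from 0, so their counts and medians describe the members and are no independent evidence of a direction. Of 30 compared genes of the axoneme and of transport within cilia, 21 were at least 2-fold lower, 0 were higher and 30 of 30 lay below 0, with a median log2 ratio of -1.38. Spag6l, a protein of the central apparatus, had -2.98, the dynein assembly factors Dnaaf1 and Zmynd10 had -2.43 and -2.31, the dynein heavy chain gene Dnah8 had -1.94, and Meig1, needed for sperm tail formation, had -1.76. Among genes for transport along the cilium, Ift172 had -1.39, Ift140 -1.36, Ift88 -0.48 and the motor gene Kif3a -0.40, and the member closest to 0 was another dynein assembly factor gene, Dnaaf5, at -0.24. Of 24 genes of glucose and lactate metabolism 11 were at least 2-fold lower and 0 higher, 10 lay above 0, and the median was -0.46; Fbp1, Pgam2 and Gk2, already among the 12 lowest genes, belong to it. Those lower included the glucose transporter Slc2a3 at -2.25 and Ldha at -1.92, while Ldhb, Slc16a1, Slc2a1 and Hk2 had 0.34, 0.37, 0.41 and 0.34.

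All 24 compared collagen and basement membrane genes lay above 0, with a median of 0.35 and 0 beyond 2-fold; Lama2 and Lama1 had 0.64 and 0.57 and Col3a1 had 0.37. Of 41 cytosolic ribosomal protein genes 38 lay above 0, with a median of 0.32, and 1 was at least 2-fold lower, the dim Rps27 at -1.09. Spike-in scaling would move each of these values by about -0.35 and so bring the matrix and ribosomal medians to about 0 or below. Among probe sets with no gene symbol that were bright enough, 9 of 547 were at least 2-fold higher and 11 lower.

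All tests in the following paragraphs were chosen after the results they bear on had been seen, although the loess alternative itself was fixed before the data were examined, and intervals cover the spread between genes only. X-linked genes lay above autosomal genes. A trend of the ratio with signal is not enough to account for this, since the X excess of 0.29 was taken over autosomal lists matched on signal. Because of this matching loess could change the excess little, and after loess it was 0.30. A smaller share of late spermatocytes could account for the chromosome as a whole when set against chosen markers. In those cells the X is silent while many autosomal genes are active. The X median exceeded that of 69 autosomal markers of spermatogonia, Sertoli, Leydig, myoid and endothelial cells by 0.029 (95% interval -0.03 to 0.12). Of these markers 53 were somatic, with a median of 0.34, and 16 were of spermatogonia, with a lower median of 0.22. The whole X, with a median of 0.35, was not tested against each group, so its result leans on the somatic markers. Macrophage and leukocyte markers, with a median of -0.08, were left out of this reference. Including them would lower it and widen the difference, by an amount that was not tested. For the 12 premeiotic X-linked genes the tables do not decide. Their median exceeded that of spermatogonia markers by 0.28 (0.05 to 0.75), that of pooled Sertoli, Leydig, myoid and endothelial markers by 0.17 (-0.03 to 0.57) and that of myoid markers by 0.0095 (-0.19 to 0.42). The Y-linked genes exceeded them by 0.46 (0.17 to 1.10), 0.35 (0.08 to 0.92) and 0.19 (-0.08 to 0.76), and spermatogonia markers may also be used in late spermatocytes, so a smaller share of spermatocytes and a weaker silencing of the sex chromosomes in UBR2-/- spermatocytes cannot be told apart for these genes.

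Macrophage and leukocyte genes did not lie above all genes with the other somatic markers. A smaller share of spermatocytes with nothing else altered would raise them alike, but their median differed from that of 53 Sertoli, Leydig, myoid and endothelial markers by -0.42 (-0.59 to -0.31). Flattening of ratios at low signal does not account for it, since the difference from the 21 of those markers in the same signal range was -0.40 (-0.62 to -0.27). A lower share of macrophages or lower expression in them on the UBR2-/- array stays open and may differ between single mice.

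Late spermatocyte genes were the group farthest below all genes among the fixed lists. The tables argue against degraded RNA, since the 3' to 5' ratio of Gapdh differed by 0.048 and that of Actb by -0.09 on the log2 scale. The late list lay below the early meiotic list by a difference of -1.65 (-2.56 to -0.87). A loss or arrest of the cells and a delayed first wave of spermatogenesis both allow this value and cannot be told apart, because only 1 age was measured. Since RNA of testes and not of single cell types was measured, lower expression within late spermatocytes stays open too. A candidate explanation is that UBR2-/- testes held fewer cells at or past the pachytene stage.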
